A study of Arabidopsis thaliana with 8 samples.

How the data were processed

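Total RNA of Arabidopsis Col and hag1 was sequenced at 4 stages, with 1 library per genotype and stage, from libraries that, per the labels, were made by BGI with Illumina protocols. The deposited files hold, per the file headers, the count of unique reads of each transcript model, and the authors gave these counts without scaling. The deposited RPKM values are those counts divided by transcript length and by the library's unique reads, which was checked on every line of the files. Per the file headers a further deposited column gives coverage as the percent of each transcript model covered by reads. Submitters' processing notes name TAIR10 as the genome; the aligner and the counter are not given in the sources used here, nor is the use of strand. Outside the gene lists, symbols came from a TAIR 10 annotation that matched 25463 of 25686 loci. Coordinates were read from the gene descriptions in the deposited files.

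Counts of the 30591 transcript models were summed per locus. Loci with more than 1 listed isoform (4184) held 2.84 to 3.32% of the reads, and the median coverage of their models was 6.34 to 6.53%, against 82.1 to 86.6% for models of other loci, so reads that several models share appear to be missing from the counts. Organelle genes held 0.297 to 0.569% of reads and the 10 most abundant transcripts 3.00 to 7.66%.

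Counts were scaled with TMM and filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 18710 genes. A quasi-likelihood model with additive terms for stage and genotype was fitted to the 8 libraries, with 3 residual degrees of freedom and a biological coefficient of variation of 0.264. It tested the genotype effect shared by stages and the 3 changes between successive stages shared by genotypes, with Benjamini-Hochberg adjustment at 0.05. In it the libraries of different stages stand in for replicates, so a genotype effect that varies by stage enters the error. A model with an added term, chosen after seeing the data, tested whether the hag1 effect differed between explants and root. Each simulated set had 100 genes changed 2-fold, 100 changed 4-fold and no change of the tested kind in all others. The tests recovered 15% of 2-fold and 69% of 4-fold genotype effects. For stage effects they recovered 0 to 1% and 30 to 51%, and each set gave 4 false calls. In the data 5562 genes passed for CIM versus root and 2133 for SIM 2 weeks versus SIM 2 days. The adjustment is less strict there, so the simulated shares do not give the recovery of these stage effects.

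Within a stage the TMM-scaled ratio of hag1 to Col was given with its exact 95% Clopper-Pearson interval, for genes with at least 50 reads in either library. A change of at least 2-fold was counted. List medians used a prior count of 2 and were set against 10000 random lists drawn within 20 expression bins. Random genes were drawn independently, so percentiles and ranges ignore correlation among members of a list and can overstate how rare a median is. Of 68 medians, 29 lay outside the range of 95% of random lists. Among members with at least 50 reads there were also 29, but only 23 were the same lists and stages (gene lists within a stage). For a gene without reads in the libraries compared, the fold was bounded with 3 reads per library.

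The 19 gene lists held 288 members, of which 8 had no unique reads in any library. They covered the root stem cell regulators, other root meristem regulators, shoot regulators, wound-induced regulators, type-A regulators with cytokinin oxidases, and cytokinin receptors with type-B regulators. Others were Aux/IAA and GH3 genes, auxin transport and response, cell division, root hairs, endodermis and root uptake, xylem and phloem, stomata and photosynthesis. The last were jasmonate and salicylate, embryo and seed, histone acetyltransferases with HAG1 partners, Polycomb with DNA methylation and deacetylation, and housekeeping. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated one. Of 72 tests, 28 passed with the preset and 0 with the estimated correlation. Deposited gene ontology terms of 10 to 500 genes (322 terms, 11030 annotated genes as background) were tested with a one-sided Fisher's exact test.

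The lists, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 6 largest called changes per direction and stage comparison with a mean CPM of at least 10 in the higher stage and 1 direction in both genotypes. It took the 8 largest per direction for genotype with 1 sign at all 4 stages and at least 50 reads, the 6 largest per direction within a stage with at least 100 reads, and up to 4 members per list and comparison. HAG1, the root stem cell regulators and the shoot regulators WUS, CUC1, CUC2, STM, ESR1 and CLV3 were always named.

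The alternatives were DESeq2 size factors, total counts, no low-count filter, a filter of at least 1 CPM in 4 libraries, models without the stage or the genotype term, fits to the 4 libraries of 2 stages, the DESeq2 Wald test (1.42.0), limma on log2(RPKM + 1) and log2(RPKM + 0.1), each library or stage left out, minimums of 20 and 200 reads, and list tests on other settings. Leaving out loci with several listed isoforms was added after seeing the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.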

Results

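RNA of Arabidopsis was sequenced along de novo shoot regeneration from roots in the wild type Columbia-0 (Col) and in hag1, a mutant of the histone acetyltransferase gene HAG1 (also known as AtGCN5). In this culture system root explants are first kept on callus-inducing medium (CIM), rich in auxin, and then moved to shoot-inducing medium (SIM), rich in cytokinin. The stages were roots, explants after 4 days on CIM, explants after a further 2 days on SIM, and explants after 2 weeks on SIM. Each of the 4 stages gave 1 library per genotype, so 8 libraries were compared, and no genotype had a replicate within a stage. Between 21336 and 22313 loci had unique reads in a library, and a locus without reads was bounded by 3 reads, or 0.398 to 0.431 counts per 1e+06 unique reads (CPM), depending on the depth of the library. Differences that both genotypes shared between stages, or that all stages shared between genotypes, were tested with the edgeR quasi-likelihood test. A ratio within a stage had no replicate check and carries only the exact interval of its counts. Nothing in the labels says that libraries came from separate cultures, so p-values measure only the spread between these libraries. Loci with several listed isoforms kept few unique reads, and near-identical gene copies and antisense neighbours could not be separated.

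HAG1 reads were scarce in every hag1 library. Roots gave 171 reads in Col and 21 in hag1, CIM explants 204 and 8, explants after 2 days on SIM 340 and 16, and explants after 2 weeks on SIM 156 and 13. The log2 ratios of hag1 to Col were -3.08 (95% interval -3.81 to -2.43), -4.57 (-5.80 to -3.57), -4.22 (-5.05 to -3.50) and -3.59 (-4.54 to -2.78). The gene (AT3G54610) lies on the forward strand of chromosome 3 at 20213560 to 20217653 in TAIR10. Over the stages it fell in hag1 with a log2 change of -3.82 (SE 0.29, edgeR adjusted p = 0.0239). HAG1 was not called without the stage term or without both libraries of any stage, where edgeR called 0 genes for genotype. For HAG1, genotype effect over stages kept its sign without each library in turn. Its adjusted p then stayed under the threshold without the Col root (0.0495) or hag1 root library (0.0493) and lay between 0.0650 and 0.157 without any of the other 6 libraries.

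**Figure D1:**
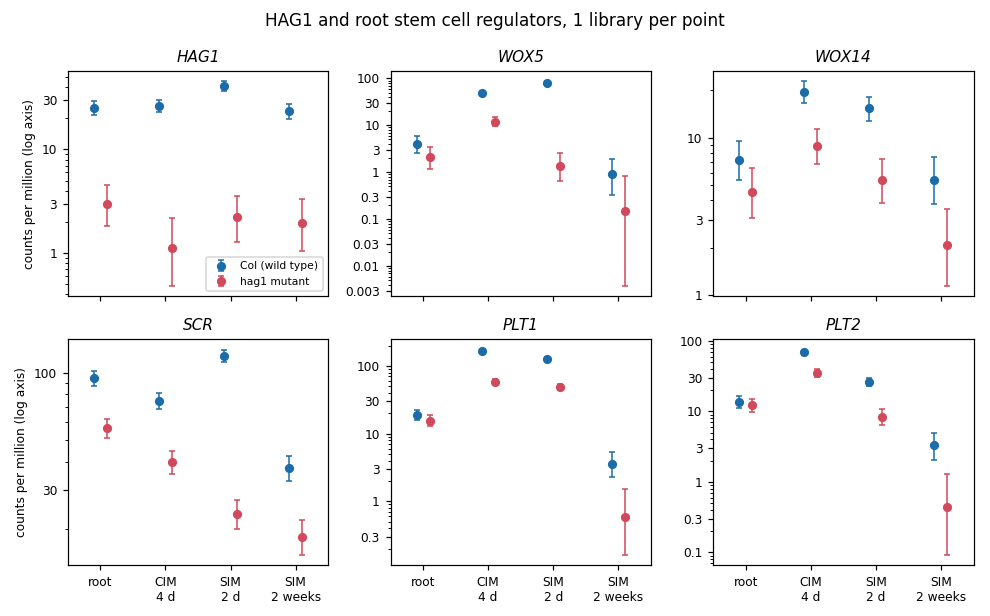
CPM, on a log axis, of HAG1 and the 5 root stem cell regulators WOX5, WOX14, SCR, PLT1 and PLT2 in the 8 libraries, by stage and genotype, with bars for the exact Poisson 95% interval of each count. HAG1 lies lower in hag1 at each of the 4 stages, and the WOX5 values of the genotypes lie farthest apart after 2 days on SIM.

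The first question was how regulators of the root stem cell niche behaved in hag1, since callus on CIM forms along a root development programme and these genes are ones the study examined. These 5 genes had lower normalised counts in hag1 at each of the 4 stages. WOX5, the homeobox gene of the quiescent centre (AT3G11260, chromosome 3, 3527575 to 3528433), had 27 reads in Col and 15 in hag1 roots, 377 and 86 on CIM, 670 and 10 after 2 days on SIM, and 6 and 1 after 2 weeks. Its log2 ratio was -0.91 (95% interval -1.92 to 0.06) in roots, -2.03 (-2.39 to -1.69) on CIM and -5.88 (-6.95 to -4.99) after 2 days on SIM. SCR, which specifies the endodermis and the niche (AT3G54220, chromosome 3, 20070158 to 20072780), had log2 ratios of -0.74, -0.90, -2.35 (-2.59 to -2.11) and -1.02 from roots to 2 weeks on SIM. PLT1 (AT3G20840, chromosome 3, 7300675 to 7303693) and PLT2 (AT1G51190, chromosome 1, 18977284 to 18980618), AP2 factors of the root meristem, were close to Col in roots, at -0.29 (-0.67 to 0.09) and -0.15 (-0.59 to 0.28). On CIM they were at -1.48 (-1.64 to -1.32) and -0.96 (-1.19 to -0.75), and after 2 days on SIM at -1.38 and -1.68. WOX14 (AT1G20700, chromosome 1, 7182558 to 7184009) had ratios of -0.67, -1.14, -1.51 and -1.37.

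Over the 4 stages the genotype effects on these 5 genes were -2.83 for WOX5 (SE 0.87, edgeR adjusted p = 0.160), -1.24 for SCR (SE 0.29, 0.108), -1.24 for PLT1 (SE 0.30, 0.116), -1.17 for WOX14 (SE 0.22, 0.0813) and -1.15 for PLT2 (SE 0.37, 0.168). Thus 0 of the 5 passed the edgeR test over all genes, while 5 of 5 fell when adjusted over the list alone. The DESeq2 Wald test called WOX5, WOX14, SCR and PLT1 lower, and limma called none of the 5. As a set they were lower than other genes (camera adjusted p = 2.11e-04, but adjusted p = 0.793 with an estimated correlation). The list holds genes that the study examined and is not independent evidence of its direction. A test of whether the hag1 effect differed between the explant stages and the root called 0 genes at an adjusted p under 0.05 and 1551 at an unadjusted p under 0.05, with edgeR as the only tool. There the adjusted p was 0.687 for WOX5, at a difference of -2.65, and between 0.603 and 0.773 for the other 4. For WOX5, genotype effect over stages was -1.65 without the Col library of 2 days on SIM and -1.66 without the hag1 library of that stage.

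Genes that differed between genotypes at all stages included several that were nearly silent in Col. HAC2, a histone acetyltransferase of the CBP family (AT1G67220, chromosome 1, 25145587 to 25150558), had 0, 1, 2 and 0 reads in Col and 16, 79, 98 and 43 in hag1, from roots to 2 weeks on SIM (edgeR adjusted p = 0.0239). The F-box gene AT1G26515 had at most 2 reads in a Col library and 40, 83, 180 and 252 in hag1. The transposable element genes AT1G64240 and AT4G07850 had at most 1 read in a Col library and up to 167 and 62 in hag1. AT2G43960, AT2G41470, AT5G40040 and AT3G47030 completed the 8 largest increases. MRN1, the marneral synthase of a root triterpene cluster, fell most (log2 -5.25, SE 0.26, edgeR adjusted p = 0.0101), with 3480 reads in Col roots and 111 in hag1 roots. The fucosidase gene FUC1 fell by 4.42 (SE 0.30), the leaf margin regulator NGA1 by a log2 of -3.90 (SE 0.40), and the amino acid transporter gene UMAMIT17 by -3.17 (SE 0.39). The GATA factor gene CGA1 was lower too, with 240 and 21 reads after 2 weeks on SIM, as were AT2G36970 and AT3G62280. CYCD3;2, a D-type cyclin, was the only member of the cell division list that passed, at -1.64 (SE 0.18, edgeR adjusted p = 0.0436).

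In all, 45 of 18710 genes rose and 36 fell in hag1 over the stages, 80 of the 81 with the same sign at all 4 stages. At an unadjusted p under 0.05 there were 3845. Of the 15 tested histone acetyltransferases and HAG1 partners, HAC2 rose and the other 14 did not pass; the list lay above other genes (camera adjusted p = 0.0386; adjusted p = 0.793 with an estimated correlation) with a median of 0.15. The endodermis list had a median of -0.99 and the xylem and phloem list one of -1.02. These lists lay below other genes (camera adjusted p = 0.00128 and 0.00124), and each of the calls had an adjusted p = 0.793 with an estimated correlation. No member of either passed over all genes, and 5 of 12 and 5 of 9 fell when adjusted over the list alone, among them CASP1 (-2.47, SE 0.40), which builds the Casparian strip, and the xylem protease gene XCP2 (-1.37, SE 0.27). In the cytokinin receptor and type-B regulator list 2 of 7 rose and 3 fell adjusted over the list alone; AHK4 was at 1.41 (SE 0.31), a locus with 3 listed isoforms, and ARR2 at -1.10 (SE 0.26). The Polycomb, DNA methylation and histone deacetylation list had a median of 0.05, and 0 of its 15 tested members passed over all genes or adjusted over the list alone. The list median and the camera direction differed in sign for shoot regulators (median -0.09), wound-induced regulators (-0.11, mean 0.12) and housekeeping genes (0.01, mean -0.07), and median and mean for type-A regulators (0.12 and -0.08); camera called none of these 4 lists. Among 322 deposited gene ontology terms, transmembrane transport was enriched in the genes that fell (4 of its 15 members, Fisher's exact test, adjusted p = 3.41e-06): PIP2B, TIP2, PCS1 and PIP2;4, which lie outside the naming rule and were chosen after their values were seen.

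The count of 81 depended on every library. It was 0 without either CIM library, either library of 2 days on SIM or the hag1 library of 2 weeks on SIM (2721 to 3172 genes at an unadjusted p under 0.05), 15 without the Col library of 2 weeks on SIM, 31 without Col root and 34 without hag1 root. The balance of directions changed too: for the genotype effect over stages more genes fell than rose with the DESeq2 Wald test (352 rose and 853 fell of 1205), with DESeq2 size factors (58 and 59), with no low-count filter (93 and 129), with limma on log2(RPKM + 1) (0 and 2), without Col root (9 and 22) and without hag1 root (9 and 25). Limma called 2 on log2(RPKM + 1) and 14 on log2(RPKM + 0.1), and without both libraries of any stage edgeR called 0 (2574 to 4062 at an unadjusted p under 0.05).

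The next comparison asked what CIM changed in roots of both genotypes. Genes of differentiated root cells fell and auxin-induced genes rose strongly. All 9 tested root hair genes fell (median log2 -8.74): the cell wall protein gene PRP3 went from 1537 reads in Col and 1098 in hag1 roots to 1 and 0 on CIM, and the root hair regulator RSL4, with 105 and 75 reads in roots and 0 on CIM, was at least 40.0-fold lower in Col and at least 25.6-fold lower in hag1. Of 12 endodermis and root uptake genes 9 fell (median -6.96). The iron transporter IRT1, a locus with 2 listed isoforms, had 971 and 843 reads in roots and 0 on CIM, at least 369-fold lower in Col and at least 288-fold lower in hag1, and the peroxidase gene PER64 of the Casparian strip fell by a log2 of -8.44 (SE 0.60, edgeR adjusted p = 0.00126). In the other direction 14 of 16 Aux/IAA and GH3 genes rose and 1 fell (median 4.31), among them GH3.3 (7.53, SE 0.79, edgeR adjusted p = 0.00305), an auxin-conjugating enzyme gene, and the auxin response repressor gene IAA30 (5.68, SE 0.59).

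Regulators of root meristems and callus rose as well. PLT1 rose by 2.47 (SE 0.41, edgeR adjusted p = 0.00999), PLT2 by 1.87 (SE 0.49), and WOX14 rose with an adjusted p = 0.0319, 3 of the 5 stem cell regulators, and 4 of 5 when adjusted over the list alone. In the list of other root meristem and lateral root regulators 7 of 14 rose and 1 fell: PLT7 (4.74, SE 0.65) and LBD18 (4.00, SE 0.84) rose, and MGP (-3.57, SE 0.95) fell. Of 7 wound-induced callus regulators 4 rose, among them ANAC071 (6.09, SE 0.71), ERF115 (3.99, SE 0.54) and WIND3 (2.48, SE 0.22). In the list of type-A response regulators and cytokinin oxidases 9 of 16 rose and 1 fell, led by CKX3 (7.47, SE 0.34, edgeR adjusted p = 7.54e-04), which degrades cytokinin. Of the 21 tested shoot meristem and leaf primordium regulators 5 rose and 1 fell. CUC2, a boundary regulator, had 1 and 0 reads in Col and hag1 roots and 124 and 141 on CIM, ESR1 was at least 19.6-fold higher in Col and at least 29.0-fold higher in hag1, and the receptor kinase gene CLV1 fell by 4.80 (SE 0.66). Of 27 cell division and replication genes 9 rose, such as MCM3 (1.68, SE 0.18) and MCM4 (1.44, SE 0.21). Of 11 genes of auxin transport, synthesis and response factors 4 rose, ARF5 by 2.62 (SE 0.35), and 1 fell, PIN2 by a log2 of -2.46 (SE 0.43). The seed and embryo list had 1 tested member of 12, AGL15, which rose by 2.17 (SE 0.53, edgeR adjusted p = 0.0291), and none of the 5 stomatal genes had enough reads to be tested.

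Genes of vessels and of photosynthesis fell. In the xylem and phloem list 7 of 9 fell, for example the cellulose synthase genes IRX1 (-3.81, SE 0.57) and IRX3 (-2.99, SE 0.29) of the secondary wall. Of 36 photosynthesis genes 28 fell, PSBR by a log2 of -3.67 (SE 0.29, edgeR adjusted p = 0.00159). In the jasmonate, salicylate and wound list 3 of 15 fell, among them the jasmonate synthesis gene AOS (-2.24, SE 0.61), and 2 of 7 cytokinin receptors and type-B regulators fell, ARR2 (-1.33, SE 0.37) and AHK3 (-0.62, SE 0.17). Of 15 Polycomb, DNA methylation and histone deacetylation genes 6 rose, led by the chromatin remodeller DDM1 (1.66, SE 0.20). Of 15 histone acetyltransferases and partners 3 rose, HAC2, HAG2 and HAF1. HAC2 went from 0 reads in roots to 1 on CIM in Col and from 16 to 79 in hag1, so its rise rests on hag1. In the housekeeping list 3 of 7 fell, ACT2, UBC9 and GAPC2, of which ACT2 and UBC9 have 2 listed isoforms each; the list median, -0.12, was 0.04 when scaled to total counts. Single genes with the largest changes were the zinc finger gene ZFP2 (0 reads in roots, at least 40.9-fold higher in Col and 123-fold in hag1), the germin-like gene AT5G39180 (at least 107-fold and 20.2-fold), the aquaporin gene TIP2;3 (3518 and 551 reads in roots, 1 and 0 on CIM) and the sugar transporter gene SWEET12 (at least 182-fold and 78.8-fold lower). Among deposited gene ontology terms, the lowest adjusted p among the genes that rose belonged to activation of innate immune response (24 of 60 members, Fisher's exact test, adjusted p = 2.79e-05) and signaling (76 of 327, adjusted p = 2.79e-05). Programmed cell death (43 of 160, adjusted p = 1.46e-04), embryo development ending in seed dormancy (15 of 31, adjusted p = 1.46e-04) and DNA-dependent DNA replication (16 of 37, adjusted p = 3.36e-04) came next, by Fisher's exact test. Plant-type cell wall biogenesis had the lowest adjusted p among the genes that fell (24 of 37, Fisher's exact test, adjusted p = 1.04e-07).

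Over all genes 2384 rose and 3178 fell from root to CIM, 940 and 1992 of them by at least 4-fold. In the comparison CIM versus root limma found no such excess of genes that fell (2983 rose and 2954 fell on log2(RPKM + 1), 2904 and 2729 on log2(RPKM + 0.1)). Camera set apart the lists of root hair genes (adjusted p = 5.33e-15), Aux/IAA and GH3 genes (1.13e-12), photosynthesis (5.31e-11), endodermis (5.99e-11), type-A regulators (2.06e-06), xylem and phloem (5.23e-05), wound-induced regulators (2.10e-04), cell division (2.10e-04), other root meristem regulators (0.00206), shoot regulators (0.00734) and the Polycomb list (0.0126). With an estimated correlation these calls had an adjusted p = 0.198 to an adjusted p = 0.419. The count of 5562 was 1906 without the Col CIM library, 2631 without Col root, 2813 without hag1 CIM and 3695 without hag1 root.

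**Figure D2:**
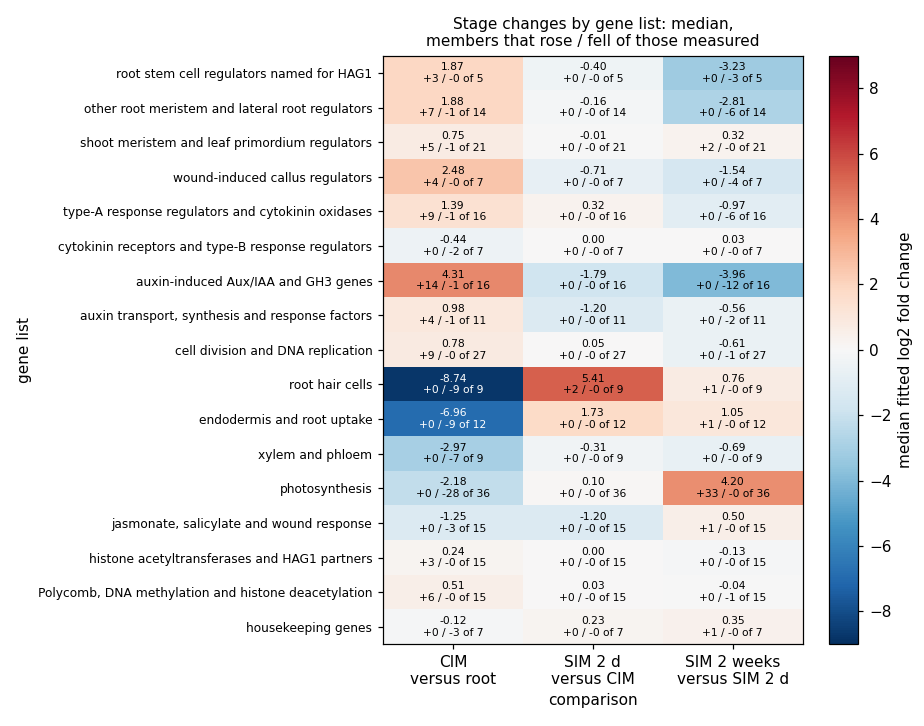
Heat map of the median fitted log2 change of each gene list in the 3 stage comparisons, with the number of members that rose and fell in each cell. Root hair genes have a median of -8.74 from root to CIM, and 33 of 36 photosynthesis genes rose from 2 days to 2 weeks on SIM.

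From CIM to 2 days on SIM few genes passed the test, among them genes of flavonoid synthesis and of cell walls. TT4, the chalcone synthase gene, had 16 and 10 reads in Col and hag1 on CIM and 5378 and 14296 after 2 days on SIM (log2 9.35, SE 0.60, edgeR adjusted p = 0.0358), and TT5, the next enzyme of the pathway, rose by 6.66 (SE 0.47). PRP3 went from 1 and 0 reads to 151 and 127, the extensin gene EXT10 from 1 and 3 to 293 and 258, and the root hair wall gene LRX1 from 2 and 1 to 81 and 60. The wall glycoprotein genes HRGP1 (6.43, SE 0.47) and AT3G54580 (6.17, SE 0.41) rose too, as neighbouring copies whose reads are uncertain. CYP78A10 was the only gene that fell, from 408 and 343 reads to 6 and 2 (-6.59, SE 0.55, edgeR adjusted p = 0.0390).

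Of 9 root hair genes 2 rose over all genes and 8 rose adjusted over the list alone (median 5.41, or 5.15 with the gene without reads at its bound; camera adjusted p = 1.49e-20; adjusted p = 0.244 with an estimated correlation). None of the 16 Aux/IAA and GH3 genes passed over all genes, and 12 fell when adjusted over the list alone (median -1.79; camera adjusted p = 1.02e-19; adjusted p = 0.244 with an estimated correlation), with IAA29 at -4.03 (SE 0.40) and GH3.2 at -2.78 (SE 0.43). Wound-induced regulators had a median of -0.71 (camera adjusted p = 0.00426; adjusted p = 0.274 with an estimated correlation), and 3 of 7, ERF115 at -2.98 among them, fell adjusted over the list alone. Auxin transport and response genes had a median of -1.20 (camera adjusted p = 0.00594; adjusted p = 0.680 with an estimated correlation). The endodermis list had a median of 1.73, or 1.22 with genes without reads at their bound (camera adjusted p = 0.00594; adjusted p = 0.768 with an estimated correlation), and CASP1 was at 4.79 (SE 0.85). The jasmonate list lay at -1.20, or -0.99 at the bound (camera adjusted p = 0.0113; adjusted p = 0.768 with an estimated correlation). Of the stem cell regulators PLT2 was at -1.70 (SE 0.48, edgeR adjusted p = 0.290). In all, 12 genes rose and 1 fell, with 1987 at an unadjusted p under 0.05. The count of 13 was 0 without any of the 4 libraries of the compared stages (1324 to 1812 at an unadjusted p under 0.05), 1 without either root library, 27 without the Col and 26 without the hag1 library of 2 weeks on SIM. For SIM 2 days versus CIM the DESeq2 Wald test called 278 genes higher and 259 lower, and limma 46 genes on log2(RPKM + 0.1).

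Between 2 days and 2 weeks on SIM most photosynthesis genes rose, and most Aux/IAA and GH3 genes and some root meristem regulators fell. Of 36 photosynthesis genes 33 rose, and 36 rose when adjusted over the list alone, including the Calvin cycle genes SBPASE (6.06, SE 0.65, edgeR adjusted p = 0.00892) and GAPB (5.83, SE 0.40) and the photosystem II gene PSBY (5.47, SE 0.31). PLT1 fell by a log2 of -5.43 (SE 0.50, edgeR adjusted p = 0.00701), PLT2 by -3.23 (SE 0.58) and WOX14 by -1.43 (SE 0.31), and all 5 stem cell regulators fell when adjusted over the list alone. Of 14 other root meristem regulators 6 fell: LBD18 went from 519 and 81 reads in Col and hag1 to 0 and 2, and BBM fell by a log2 of -5.66 (SE 0.79). The lateral root regulator PUCHI went from 832 and 133 reads to 3 and 0.

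Of 16 Aux/IAA and GH3 genes 12 fell, GH3.2 by a log2 of -6.77 (SE 0.55); the list median was -3.96, or -3.16 with IAA29 and IAA20, which had no reads after 2 weeks, at their bounds of at least 12.1-fold and 9.99-fold lower in Col. CKX3 fell by a log2 of -5.96 (SE 0.32), 1 of 6 genes of the type-A regulator and cytokinin oxidase list that fell. Of 7 wound-induced regulators 4 fell, such as ANAC071 (-3.61, SE 0.70), and in the cell division list 1 of 27, CDKB1;1 (-0.87, SE 0.16). Among 21 shoot regulators 2 rose: STM, the meristem maintenance gene, with 1 and 1 reads after 2 days and 29 and 15 after 2 weeks (edgeR adjusted p = 0.0265), and RAP2.6L (1.11, SE 0.24). The lipid transfer gene LTP3 fell by a log2 of -7.79 (SE 1.08). AT1G80130 went from 1 read in each genotype to 1165 in Col and 215 in hag1, the receptor kinase gene CRK22 from 0 to 230 and 26 (at least 94.7-fold and 9.35-fold higher), and the defensin-like gene AT3G05730 from 3 in each to 4463 and 129. Among the genes that rose, generation of precursor metabolites and energy (29 of 78 members, Fisher's exact test, adjusted p = 3.65e-10) and photosynthetic electron transport (14 of 27, adjusted p = 7.58e-07) had the lowest adjusted p. Among those that fell these were embryo development ending in seed dormancy (10 of 31), response to organic substance (14 of 65) and response to reactive oxygen species (13 of 57), each with an adjusted p = 1.57e-04 by Fisher's exact test.

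In total 1326 genes rose and 807 fell. Camera called the lists of photosynthesis (adjusted p = 2.29e-47), Aux/IAA and GH3 genes (4.15e-16), other root meristem regulators (4.05e-07), stem cell regulators (4.15e-05), type-A regulators (2.22e-04), cell division (4.45e-04) and wound-induced regulators (7.70e-04). With an estimated correlation these had an adjusted p = 0.294 to an adjusted p = 0.695. The count of 2133 became 147 without the Col library of 2 days on SIM, 447 without Col after 2 weeks, 847 without hag1 after 2 weeks and 977 without hag1 after 2 days. In the comparison SIM 2 weeks versus SIM 2 days more genes fell than rose with limma (1018 rose and 1151 fell on log2(RPKM + 1), 952 and 1146 on log2(RPKM + 0.1)).

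Within roots endodermis and jasmonate genes lay lower and shoot regulators higher in hag1. MRN1 was 32.7-fold lower in hag1 (95% interval of the log2 ratio -5.31 to -4.76) and the bHLH gene AT4G37850 18.5-fold lower, while the glutathione transferase gene GSTF14 (35 and 865 reads) and the beta-glucosidase gene DIN2 (53 and 1135) were 23.7-fold and 20.6-fold higher. Endodermis genes had a median log2 ratio of -1.09 (percentile 0 among 10000 matched random lists), with 8 of 12 at least 2-fold lower, CASP1 at -1.54 and CASP4 at -1.78, but the nitrate transporter gene NRT2.1 at 2.90. The jasmonate list lay at -0.76: JAZ7, a jasmonate response repressor, was at -2.20, yet the pathogenesis gene PR2 at 5.40 (1 and 44 reads). Shoot regulators lay higher, at 0.76 (percentile 100), with 17 of 21 higher in hag1, among them the growth regulator ANT (1.84, interval 1.54 to 2.14) and RAX1 (2.05, 1.41 to 2.74). The type-A regulator list (0.32) and the acetyltransferase list (0.38) also lay above, and the stem cell (-0.64) and root hair (-0.51) lists below, the range of 95% of random lists. In the comparison hag1 versus Col at root, of 12819 genes with at least 50 reads in either library, 563 were at least 2-fold higher and 1004 at least 2-fold lower in hag1. Scaled to total counts alone, which moved the median of all genes by 0.14 in roots, -0.11 on CIM and -0.10 after 2 days on SIM, these were 749 and 777.

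On CIM hag1 had less of several root, auxin and shoot regulators. The auxin synthesis genes TAA1 (81 reads in Col, 2 in hag1; log2 ratio -5.24, interval -8.31 to -3.34) and YUC8 (206 and 29; -2.73) were lower, and the list of auxin transport, synthesis and response factors had a median of -0.94 (percentile 0.03). JKD, a zinc finger partner of SCR and SHR, was at -2.20 and SHR at -1.31, in a list of root meristem regulators with a median of -0.44. In the shoot regulator list (median -0.52) the epidermal gene PDF1 was at -1.86 and LSH4 at -3.25. The cell division list lay at -0.38, with CYCD3;2 at -1.73 and CYCD3;3 at -1.53, and xylem and phloem genes at -1.14. Against these, the jasmonate list lay higher in hag1, at 0.62 (percentile 99.98), with JAZ7 at 3.25 (9 and 80 reads) and LOX3 at 1.80. Of its 15 members 11 were higher, while the other 4 were each at least 2-fold lower. The cellulose synthase gene CESA9 (4 and 141 reads) was 37.7-fold higher, and the beta-glucosidase gene BGLU44 had 197 reads in Col and 1 in hag1 (interval of the log2 ratio -12.83 to -5.03). Counted over 12495 genes, 626 were at least 2-fold higher and 954 lower.

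After 2 days on SIM root meristem, auxin-induced and jasmonate genes lay lower in hag1. The stem cell list had a median of -1.65 and the list of other root meristem regulators one of -1.48, or -1.39 with genes without reads at their bound, with 11 of 14 at least 2-fold lower: JKD (590 and 92 reads), LBD18 at -2.49 (519 and 81 reads) and LBD16 at -2.25. Auxin-induced genes lay at -0.99 (percentile 0), with GH3.1 at -3.43 (2433 and 199 reads) and GH3.3 at -2.06. The jasmonate list lay at -1.81, or -1.46 at the bounds, with LOX3 at -4.04 (318 and 17 reads). Wound-induced regulators lay at -0.57, cell division genes at -0.37, endodermis genes at -0.79 and xylem and phloem genes at -1.03, all under the range of 95% of random lists. PDF1 had 3122 reads in Col and 115 in hag1 (-4.58), the bHLH gene BHLH32 616 and 12 (-5.50). Higher in hag1 were CESA9 (1 and 113 reads), the photosystem II gene PSBO2 (2.22, interval 1.69 to 2.79) and the cytokinin receptor gene AHK4 (2.31, with 3 listed isoforms). At least 2-fold ratios were found for 1881 of 12470 genes, 683 higher and 1198 lower.

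After 2 weeks on SIM photosynthesis genes and all 3 lists of differentiated root cells lay lower in hag1. Of 36 photosynthesis genes 35 were lower (median -0.75, percentile 0), with LHCB2.2 at -1.93 (235 and 62 reads) and the near-identical copies LHCB1.1 and LHCB1.2 at -2.64 and -2.28. Endodermis genes lay at -2.24, CASP1 at -3.51 (203 and 18 reads), xylem and phloem genes at -1.61 and root hair genes at -1.30. The stem cell list lay at -1.42, with 5 of 5 members at least 2-fold lower, but mostly on few reads. In Col and hag1 WOX5 had 6 and 1 reads, PLT1 24 and 4, PLT2 22 and 3, WOX14 36 and 14, and SCR 249 and 124. The jasmonate list lay at -1.33, with LOX2, a chloroplast lipoxygenase gene of jasmonate synthesis, at -3.73 (529 and 40 reads). The iron homeostasis genes NAS1 (115 reads in Col, 1 in hag1) and bHLH38 (231 and 4) and the glucosinolate synthesis gene CYP79F2 (260 and 6) were among the 6 largest decreases. Cell division genes lay higher in hag1, at 0.36 (percentile 100), with 22 of 27 higher and CYCB1;1 at 0.83 (exact 95% interval from 0.47), although CYCD3;2 was at -1.66. The pectin-degrading genes PGAZAT (4 and 109 reads) and ADPG1 (22 and 465) were 27.1-fold and 21.0-fold higher. Ratios of at least 2-fold were found for 1733 of 12186 genes, 317 higher and 1416 lower in hag1.

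**Figure D3:**
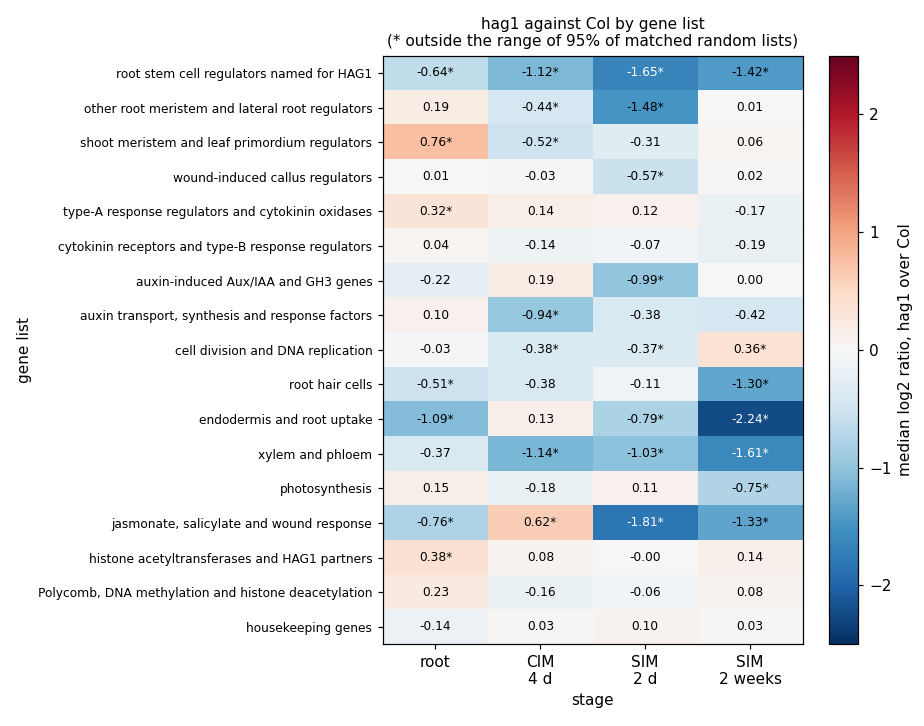
Median log2 ratio of hag1 to Col for each gene list at the 4 stages, with an asterisk where the median lies outside the range of 95% of 10000 random lists of the same size and expression. Stem cell regulators lie below 0 at all stages, and shoot regulators move from 0.76 in roots to -0.52 on CIM.

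Regulators of shoot meristem formation were read at low counts on SIM. After 2 days WUS, the stem cell organiser of the shoot, had 1 read in Col and 9 in hag1, and after 2 weeks 16 and 13. CUC1 had 35 and 11 reads and then 21 and 41, CUC2 144 and 219 and then 52 and 121, and STM 1 and 1 and then 29 and 15. ESR1, an AP2 factor that promotes shoot regeneration, had 57 reads in Col and 114 in hag1 after 2 days, and 1 and 60 after 2 weeks (log2 ratio 5.90, interval 3.36 to 11.22). CLV3 had no unique reads in any library, which does not show that it was not expressed. The photosynthesis gene LHCA1 had none in any library either.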

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

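Of the tests in this part, only those on reads from another locus matching a short stretch and on a few genes taking most of the reads were chosen before their result was seen; the other tests were chosen after it. In 3 gene lists the median log2 ratio of hag1 to Col lay outside the random range in opposite directions at different stages, and none of these differences was tested. Shoot regulators lay at 0.76 in roots and -0.52 on CIM, a difference of 1.28. The jasmonate and salicylate list lay at 0.62 on CIM and -1.81 after 2 days on SIM, a difference of 2.43. After 2 days on SIM 2 of its 15 members had no reads in 1 library. With these at their bound the median there was -1.46, so the size of the difference rests partly on genes with few reads. Cell division genes lay at 0.36 after 2 weeks on SIM and -0.38 on CIM, a difference of 0.74.

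The genotype effect over stages called 81 genes. Among the 8 splits that part the genotypes at every stage the real one gave 81 and the highest of the others 0, with 1 split as large as the real one, and 8 splits are too few for a share under 0.05.

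Of the genes called higher in hag1 over the stages, 11 had at most 3 reads in every Col library. They had more in every hag1 library, and HAC2 and AT1G26515 were among them. The set was taken from called genes only. A chromosome segment carried along with the mutation would place them near HAG1, and 0 of 11 lay within 2 Mb of it, where 4.44% of tested genes lie. Reads from another locus matching a short stretch would cover little of each transcript, and the median coverage was 86.3% (lowest 36.7%). Lower expression of Polycomb, DNA methylation and deacetylation genes as a set would give that list a negative median. It was 0.0471 (lower quartile -0.05, lowest member -0.31). Silencing genes outside the list were not covered, and its members EMF2, VRN2 and HDA19 have several listed isoforms. Loss of HAG1 itself, which the design names, and other background differences of the mutant line stay open and may each be the source; neither was tested.

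Root meristem regulators lay lower in hag1 after 2 days on SIM (pooled median log2 -1.53, 18 of 19 lower). Fewer dividing cells of every kind in hag1 would lower cell division genes by as much. Their median was -0.37 (lower quartile -0.47), with 24 of 27 lower. Losing only those dividing cells that express root meristem regulators could lower the lists unequally, and these values do not decide on that. Under the other scalings of the libraries the highest median was -1.52. More of the original root tissue would raise the genes of differentiated root cells above their ratio in roots; their median change from it was -0.17 (quartiles -0.77 to 0.81, 16 of 30 lower), which decides nothing. More root tissue, a loss of some dividing cells and an effect of the mutation stay open. With 1 library per genotype at this stage a difference between cultures could also give the same values.

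After 2 weeks on SIM 81.7% of genes with a 2-fold ratio were lower in hag1. A few genes taking most of the reads in 1 library would end this skew once removed, and without 114 top loci it was 83.0%. The 10 most abundant transcripts held only 5.69% of the reads in Col and 7.66% in hag1 at this stage. No few genes took most of the reads, so the removal itself could change little. Poorer coverage of the hag1 library would lower the percent covered; the median difference was 0.05 points, but with a median of 94.3% covered in Col, over loci with at least 50 reads in both libraries, the measure is near its ceiling and decides nothing. Tissue at an earlier point of the same course would lower photosynthesis genes and raise the lists that fell from 2 days to 2 weeks on SIM. Photosynthesis genes had a median of -0.75 (35 of 36 lower) and cell division genes, which fell, one of 0.36 (22 of 27 higher). Other lists that fell did not lie clearly higher: wound-induced regulators at 0.02 and type-A regulators at -0.17. Of 16 Aux/IAA and GH3 genes 7 lay lower and 7 higher. Their median of 0.0 was set by IAA29 and IAA20, which had no reads in either library, so that median decides nothing. Root meristem genes, already lower in hag1 after 2 days on SIM, had a pooled median of -0.0791 (11 lower and 7 higher of 19). Among them the stem cell list lay at -1.42, with 5 of 5 lower. Values on both sides leave this undecided. Poorer coverage, an earlier point and the mutation itself stay open.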

How the results depend on the processing

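The alternative without loci of several listed isoforms was chosen after seeing the data; the others were planned. For the genotype effect over stages (81 genes) the count was 222 with no low-count filter, 0 with no stage block, 2 and 14 with limma on log2(RPKM + 1) and log2(RPKM + 0.1), 1205 with the DESeq2 Wald test and 13 on loci with 1 listed isoform; leave-one-out counts ran from 0 to 34. CIM versus root (5562) ran from 1906 to 5130 with 1 library left out and stayed within 1.5-fold under the other alternatives. SIM 2 days versus CIM (13) gave 72 with no low-count filter, 0 with no genotype block, 0 with only the 4 libraries of the 2 stages, 46 with limma on log2(RPKM + 0.1) and 537 with DESeq2, and 0 to 27 with 1 library left out. SIM 2 weeks versus SIM 2 days (2133) gave 1044 with no genotype block, 1263 with only the 4 libraries, and 147 to 2041 with 1 library left out. Settings that leave out libraries or a term also leave fewer residual degrees of freedom or a larger error; beyond that the cause was not tested.

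With a minimum of 200 reads fewer genes could count: hag1 versus Col at root gave 723, hag1 versus Col at CIM 660, hag1 versus Col at SIM 2 days 895 and hag1 versus Col at SIM 2 weeks 646. With a minimum of 20 reads, CIM gave 2390 and 2 weeks on SIM 2748. Gene lists in tested comparisons fell from 28 calls to 0 with an estimated correlation.

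For WOX5, SIM 2 days versus CIM was -0.40 and reversed to 0.45 with no genotype block; with 1 library left out it ran from -3.29 to 0.91, and it was 0.13 without the hag1 CIM library. For SCR, SIM 2 days versus CIM was 0.06 and reversed to -0.0233 with only the 4 libraries and to -0.0152 with limma on log2(RPKM + 0.1); with 1 library left out it ran from -0.78 to 0.69, and it was -0.19 without the Col CIM library. From CIM to 2 days on SIM, WOX5 went from 48.7 to 81.4 CPM in Col and from 11.9 to 1.38 in hag1. SCR went from 74.5 to 119 CPM in Col and from 39.8 to 23.3 in hag1. Each fitted value thus averaged opposite changes of the genotypes, and no further cause was tested. Among tested values of named genes with no library left out, 502 kept direction and side of the threshold, 78 lost the call, 9 gained it and 3 reversed; with libraries left out these were 389, 242, 4 and 4. Of their ratios within a stage, 249 stayed within their counting interval and 35 moved beyond it. Genes with few reads are limited by depth: 3 reads are 0.398 to 0.431 CPM.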

Other observations

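The values below were looked at after the results were seen, and no explanation was tested here. The 11 genes called higher in hag1 with at most 3 reads in every Col library and more in every hag1 library held 3 transposable element genes. Among all 18710 tested genes, called or not, there were 150. That base was not limited to genes near silent in Col, so the shares cannot be compared directly. Of the genes called lower in hag1, 0 had the opposite pattern. Across 14831 genes, which are not independent replicates, the stage changes of the genotypes had a Pearson correlation of 0.868 from root to CIM, 0.521 from CIM to 2 days on SIM and 0.740 from 2 days to 2 weeks on SIM. The hag1 effects at different stages had Pearson correlations across genes from 0.204 (root and CIM) to 0.509 (CIM and 2 days on SIM). The SD of the log2 stage changes in hag1 relative to Col was 0.890, 1.18 and 0.812 in the 3 comparisons.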
